A study of Mus musculus with 16 samples.

How the data were processed

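Gene expression was measured in the embryonic mouse kidney at embryonic day 11.5, when the ureteric bud (UB), an epithelial outgrowth that will branch into the collecting ducts, has entered the metanephric mesenchyme (MM), which gives rise to the nephrons and stroma. Per the labels, 16 samples fall into 4 groups. The first group holds 4 wild-type UB samples, each pooled from 3 to 9 buds. The second holds 3 wild-type MM samples, prepared from individual mesenchymes. Both were separated by hand after treatment of the kidney rudiment with collagenase at 0.5 mg/ml and 37 °C. The third group holds 4 wild-type MM samples taken by laser capture, in which a laser lifts chosen areas off a tissue section. Each of these pooled 3 to 4 mesenchymes from sections of kidney rudiments 7 µm thick. The last group holds 5 samples of Hoxa11/Hoxd11 double null MM, also laser-captured from 7 µm sections, but of whole urogenital ridges. The labels give the source piece and the pooling differently for the null and the wild-type captures, so these differ together with genotype. Pooling also differs between UB and hand-dissected MM, and between laser-captured and hand-dissected wild-type MM. The series text describes the replicates of each group as separate embryos. Strains, litters, slides and scan dates are not given in the sources used here, so no batch could be tested.

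RNA was amplified in 2 rounds and hybridized to Affymetrix mouse arrays with 45101 probe sets, 1 array per sample, per the labels' protocols. Such amplification starts from the 3' end of transcripts and can shift the level of a probe set according to its distance from that end. The deposited values are linear MAS5 signals (intensity), per the submitters' processing notes; the MAS5 version and detection calls are not given in the sources used here. The deposited intensities had been scaled by the authors so that the mean of each array, after removal of 2% of the values at each tail, lies at 1500; this was read from the values, where the spread of that mean was 0.00013% between arrays. This scaling assumes that total expression is equal between samples. Median signals ran from 112.7 to 209.2 over the 16 arrays. No pair of arrays held identical values. Arrays give no read depth, and the number of arrays per group limits the precision.

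Gene names came from the platform's annotation table. Of the 45037 probe sets left after removal of 64 control probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none here. Probe sets with several symbols or none were tested but not named. Identifiers of 34754 probe sets matched the mouse gene table of assembly GRCm38.p6, which changed 0 symbols and which was otherwise used only to find neighbouring genes; probe coordinates were not used here. Each of 18193 genes was counted through 1 representative probe set, that with the highest mean log2 value over the 16 arrays, and disagreement with other probe sets of the same gene was counted.

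Signals were converted to log2(signal + 36.3), where the offset is the 25th percentile of all values. Fold changes are on this scale, which understates the change of dim genes. No further normalization was applied, because the trimmed means were already equal. A probe set was kept when it exceeded its array's own median in at least as many arrays as the smaller group holds. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with Benjamini-Hochberg adjustment over the kept probe sets and a threshold of 0.05. All adjusted p values of single genes come from limma. Standard errors are limma's moderated ones, and SD is the spread between arrays. Figures were drawn with matplotlib 3.10.9, and tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

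There were 3 comparisons, each fitted on its own arrays only: UB against MM, both dissected by hand; null against wild-type MM, both laser-captured; and laser-captured against hand-dissected wild-type MM. A further analysis related the first contrast to the second, which share no arrays. The other pairs of contrasts share arrays and were not set against each other. In the wild-type and null captures some replicate numbers coincide, but no label says that they pair embryos.

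The gene lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined, except the tests and fits that the closing parts name as chosen later. There were 31 lists: ureteric bud, epithelial junction and keratin, nephron progenitor, renal stroma, mesenchymal matrix, renal vesicle induction, Hox11 network, the Hoxa, Hoxb, Hoxc and Hoxd clusters, Ret and FGF targets, Wnt targets, hedgehog, BMP and TGF-beta, retinoic acid, cell cycle, p53 and apoptosis, hypoxia and glycolysis, immediate-early and stress, endothelial, erythroid, macrophage, gonad and coelomic, germ cell, adrenal and steroidogenic, neural crest and neuronal, muscle and somite, smooth muscle, posterior and cloacal, and sex-linked genes. Some genes stand in more than 1 list. Lists were tested with limma's camera, which asks whether the members moved one way relative to all other genes, at a preset inter-gene correlation of 0.01, with adjustment over the 31 lists; each call was repeated with the correlation estimated from the arrays. Hoxa11 and Hoxd11 were left out of the lists when null and wild-type mesenchyme were compared. Members past the threshold were counted over all probe sets and also adjusted over the list alone.

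The genes named are Hoxa11 and Hoxd11; the 8 largest increases and 8 largest decreases among genes past the threshold whose groups do not overlap, without clone names and predicted genes; up to 4 members with the smallest adjusted p of the ureteric bud, nephron progenitor, renal stroma and Hox11 network lists; and up to 2 of any other list described. Not all genes the rule allows are printed.

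The same code was tested on simulated arrays built from the means and spreads of the kept probe sets, with 200 probe sets changed. For UB against MM it recovered 26 of 100 changes of log2 1 and 72 of 100 of log2 2, and called 8 unchanged probe sets. For null against wild type it recovered 21 and 58 of 100, and called 4 unchanged probe sets. For the 2 isolation methods it recovered 20 and 52 of 100, and called 1 unchanged probe set. Only 200 probe sets were changed, and noise was drawn for each probe set on its own. These rates therefore need not hold for the real arrays. Alternatives covered 3 other scalings, the offset, the filter, the variance model, array weights, a fit of all 16 arrays, an unequal-variance test, other array selections, leaving out each array, and other settings of the list tests. Array measures such as 3' to 5' ratios were compared with two-sided exact permutation tests.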

Results

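Transcript levels were measured on 16 arrays from E11.5 mouse kidney rudiments: 4 of wild-type ureteric bud (UB) and 3 of wild-type metanephric mesenchyme (MM) dissected by hand, and 4 of wild-type and 5 of Hoxa11/Hoxd11 double null MM taken by laser capture. Hoxa11 and Hoxd11 are paralogous homeobox transcription factors, and embryos lacking both have severely reduced kidneys. The stated aims were to find genes particular to either structure and to find candidate targets of the Hox genes. Values are MAS5 signals, given as mean ± SD over arrays, and differences are on the log2 scale with their SE.

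In UB against MM, epithelial and ureteric bud genes were higher in the bud, and nephron progenitor, stromal, Hoxa and Hoxc genes in the mesenchyme. With an estimated correlation the epithelial and stromal lists passed (adjusted p = 0.0304 each), and the ureteric bud (0.0531), nephron progenitor (0.0531), Hoxa (0.0640) and Hoxc (0.0597) lists did not. Calb1, which encodes the calcium-binding protein calbindin and marks the bud and its branches, was 323-fold higher in UB, at 61593 ± 6976 (SD, n = 4) against 155 ± 27.3 (SD, n = 3; log2 difference 8.33 ± 0.19 SE, limma adjusted p = 6.34e-10). Ret, the receptor through which the mesenchymal growth factor GDNF drives bud outgrowth, was 115-fold higher, at 28147 ± 3761 against 208 ± 33.4. Over the alternatives the log2 difference ran from 5.00 to 8.64 for Calb1 and from 5.07 to 7.08 for Ret. These folds thus depend on the processing and on the arrays used. In the other direction Six2, which maintains nephron progenitors, stood at 582 ± 116 in UB and 21975 ± 1549 in MM (log2 difference -5.17 ± 0.22 SE). Foxd1, a marker of stromal progenitors, stood at 92.9 ± 50.3 and 12067 ± 2935 (-6.60 ± 0.32 SE).

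In all, 2952 probe sets were higher and 2749 lower in UB, of 23851 tested with limma. Counted as genes, 1727 were higher and 1820 lower of 12435. In 32.1% of the tested probe sets the arrays of the 2 groups did not overlap, where chance gives 5.71%. For 11 of the called genes another probe set was called in the opposite direction.

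On the log2 scale with its offset, which sets the order of genes near background, the largest increases in UB were for Esrp1, an epithelial splicing regulator (log2 difference 8.72 ± 0.24 SE), Calb1, the tight junction claudins Cldn3 (8.24 ± 0.26 SE) and Cldn7 (7.82 ± 0.23 SE), and Aldh1a1, an enzyme of retinoic acid synthesis (7.99 ± 0.31 SE). Mal, a membrane protein of apical sorting, Cdh16, a kidney cadherin, and Cldn8 followed, at 7.73 ± 0.25, 7.36 ± 0.42 and 7.25 ± 0.39 SE. The largest decreases were for the forkhead factor Foxc2 (-7.09 ± 0.59 SE), Foxd1, and Bmper, a secreted BMP-binding protein (-6.59 ± 0.37 SE). The atypical cadherin Fat4, the homeobox genes Hoxc10 and Hoxd10, the adhesion molecule Chl1 and the arginase Arg1 were lower by between -6.54 and -6.27. The adjusted p of these 16 genes ranged up to 4.12e-06.

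**Figure D1:**
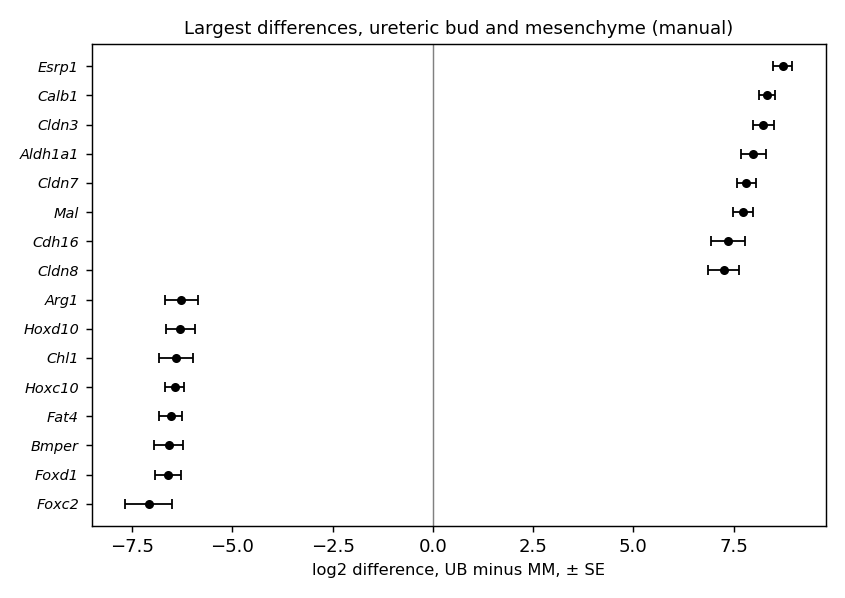
Log2 differences between ureteric bud (n = 4) and mesenchyme (n = 3), both dissected by hand, for the 8 largest increases and 8 largest decreases. Points are limma estimates and bars ± SE. The estimate is 8.72 for Esrp1 and -7.09 for Foxc2; the offset sets the order of genes near background.

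Of the 31 fixed lists, 15 passed the list test, and 2 of these, the epithelial and stromal lists, also passed with an estimated correlation. Of 18 measured ureteric bud genes, 17 were higher in UB, also when adjusted over the list alone, among them Tfap2a, a transcription factor, at 13645 ± 1034 against 288 ± 62.7 (camera adjusted p = 5.61e-18; adjusted p = 0.0531 with an estimated correlation). Of 28 epithelial junction and keratin genes, 27 were higher, also adjusted over the list alone (camera adjusted p = 3.25e-30; adjusted p = 0.0304 with an estimated correlation). Of 16 Ret and FGF targets, 9 were higher and 0 lower, with 9 and 1 adjusted over the list alone (camera adjusted p = 0.000302; adjusted p = 0.0563 with an estimated correlation). They included Wnt11, a Wnt ligand made at bud tips (log2 difference 2.76 ± 0.25 SE), and Spry1, an inhibitor of Ret signalling (2.31 ± 0.17 SE). Of 13 Wnt targets, 7 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.00875; adjusted p = 0.277 with an estimated correlation). Those higher included Rnf43, a ubiquitin ligase that removes Wnt receptors (4.79 ± 0.30 SE), and Tnfrsf19, a TNF receptor family member (3.11 ± 0.32 SE).

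Of 19 nephron progenitor genes, 16 were lower and 1 higher in UB, also adjusted over the list alone (camera adjusted p = 9.41e-16; adjusted p = 0.0531 with an estimated correlation). Besides Six2 and Hoxc10, the mesenchymal cadherin Cdh11 (log2 difference -5.67 ± 0.23 SE) and Itga8, an integrin subunit required for bud invasion (-5.43 ± 0.22 SE), were lower. Of 18 stromal genes, 15 were lower, and 16 adjusted over the list alone (camera adjusted p = 7.14e-14; adjusted p = 0.0304 with an estimated correlation), among them the Hox cofactors Meis1 (-6.13 ± 0.28 SE) and Meis2 (-5.69 ± 0.25 SE). Of 26 matrix genes, 20 were lower and 1 higher, with 21 and 1 adjusted over the list alone (camera adjusted p = 4.54e-12; adjusted p = 0.0704 with an estimated correlation). The collagens Col1a1 (-5.55 ± 0.23 SE) and Col5a2 (-4.93 ± 0.27 SE) led them. Of 17 BMP and TGF-beta genes, 8 were lower and 2 higher, with 9 and 2 adjusted over the list alone (camera adjusted p = 0.00989; adjusted p = 0.200 with an estimated correlation). Tgfbi, a matrix protein induced by TGF-beta (-5.49 ± 0.27 SE), and the ligand Bmp4 (-3.26 ± 0.25 SE) were lower.

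Of the 4 Hox clusters, Hoxa and Hoxc passed the list test and Hoxb and Hoxd did not. Of 7 Hoxa genes 6 were lower in UB, and of 6 Hoxc genes 5 were lower, with the same counts adjusted over the list alone (camera adjusted p = 2.69e-05 and 2.32e-06; adjusted p = 0.0640 and 0.0597 with an estimated correlation). Hoxa10 (log2 difference -5.62 ± 0.36 SE), Hoxa9 (-5.22 ± 0.35 SE) and Hoxc8 (-5.07 ± 0.31 SE) were among them. Of 7 Hoxb genes, 2 were higher and 1 lower, with 3 and 1 adjusted over the list alone; Hoxb4 was higher (2.13 ± 0.25 SE) and Hoxb1 lower (-3.28 ± 0.32 SE), and the list did not pass (camera adjusted p = 0.282). Of 7 Hoxd genes, 3 were higher and 3 lower, with 4 and 3 adjusted over the list alone, and the median of 0.78 and mean of -1.13 differed in sign (camera adjusted p = 0.881). Hoxa11 stood at 139 ± 42.9 in UB and 787 ± 176 in MM (-2.24 ± 0.27 SE), and Hoxd11 at 25.9 ± 17.2 and 436 ± 59.8 (-2.97 ± 0.33 SE). Hoxd11 in UB averaged below the offset, and its difference ran from -4.72 to -1.76 over the alternatives.

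Of the lists of other cell types, the following 5 passed, all lower in UB and none with an estimated correlation. Of 19 endothelial genes, 16 were lower, and 17 adjusted over the list alone, with Kdr, a VEGF receptor, at log2 difference -2.90 ± 0.31 SE and Ramp2 at -2.50 ± 0.23 SE (camera adjusted p = 2.59e-07; adjusted p = 0.237 with an estimated correlation). Of 10 erythroid genes, 7 were lower, and 10 adjusted over the list alone, with the red cell genes Ermap and Slc4a1 at -2.45 ± 0.36 and -2.04 ± 0.30 SE (camera adjusted p = 3.19e-05; adjusted p = 0.226 with an estimated correlation). Of 8 macrophage genes, 5 were lower on either count (camera adjusted p = 0.00134, and 0.277 with an estimated correlation). Csf1r, a macrophage growth factor receptor, differed by -4.35 ± 0.36 SE and Laptm5 by -4.27 ± 0.32 SE. Their other probe sets differed less, by -2.71 and -0.24 for Csf1r (limma adjusted p = 9.67e-05 and 0.559). For Laptm5 these were -1.32 and -0.43 (limma adjusted p = 0.00155 and 0.309). Of 5 smooth muscle genes 4 were lower on either count, with Acta2 at -4.02 ± 0.59 SE and Mylk at -3.10 ± 0.36 SE, and of 7 gonad and coelomic genes 4 were lower and 1 higher on either count (camera adjusted p = 0.00679 and 0.0293; adjusted p = 0.0959 and 0.164 with an estimated correlation).

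The other lists did not pass, and with the Hoxb and Hoxd clusters they number 16 of 31, at camera adjusted p of 0.0953 to 0.895. Renal vesicle induction genes went both ways, 10 higher and 6 lower of 22, with 12 and 7 adjusted over the list alone. Pou3f3 (log2 difference 6.64 ± 0.20 SE) and Lhx1 (6.40 ± 0.34 SE), transcription factors of early tubules, were higher in UB. The Hox11 network also split, with 5 higher and 6 lower of 12, and 6 and 6 adjusted over the list alone. Wt1, a transcription factor of the mesenchyme, was lower (-4.57 ± 0.25 SE). Of 10 hedgehog genes 3 were higher and 6 lower, with 3 and 7 adjusted over the list alone. The ligand Shh was higher (5.00 ± 0.45 SE) and the receptor partner Gas1 lower (-2.63 ± 0.20 SE). Immediate-early and stress genes had 3 higher and 8 lower of 28, with 3 and 9 adjusted over the list alone. Fos stood at 11840 ± 3352 in UB and 32684 ± 5142 in MM and Fosb at 2721 ± 2136 and 17990 ± 2918. Cell cycle genes had 0 of 27 called with limma and sex-linked genes 0 of 4, with 2 and 0 at an unadjusted p below 0.05. Of all tested probe sets, 8614 of 23851 had an unadjusted limma p below 0.05. Hypoxia and glycolysis had 7 higher and 3 lower of 18, with 9 and 3 adjusted over the list alone. Retinoic acid had 3 and 2 of 12, p53 and apoptosis 3 and 4 of 14, with 4 and 4 adjusted over the list alone, and neural crest and neuronal 5 and 5 of 13, with 5 and 6. Adrenal had 2 and 1 of 7, posterior and cloacal 1 and 2 of 5, muscle 1 and 1 of 5 and germ cell 1 and 0 of 5. The medians and tests of the Hoxd, retinoic acid, cell cycle, germ cell and muscle lists differed in sign.

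The direction of Fos and Fosb depended on the mesenchyme used: against all 7 wild-type MM arrays of both methods the differences were 2.46 (adjusted p = 0.335) and 1.36 (adjusted p = 0.661), against -1.50 and -2.95 on hand-dissected arrays alone. The ratio of 3' to 5' Gapdh probe sets, a measure of RNA quality, averaged 8.72 in UB and 42.5 in MM (two-sided exact permutation p = 0.0286, adjusted over 18 tests 0.0735). The same ratio for Actb averaged 13.1 in UB and 13.8 in MM (two-sided exact permutation p = 0.686), so the 2 measures differ on RNA quality. Array weights raised the count of called probe sets to 10132, and the unequal-variance test lowered it to 2488.

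In null against wild-type mesenchyme, the targeted gene Hoxa11 was lower in the null captures, at 124 ± 44.5 (SD, n = 5) against 709 ± 147 (SD, n = 4; log2 difference -2.23 ± 0.34 SE, limma adjusted p = 0.0114). The antisense transcript of the locus, Hoxa11os, fell from 2751 ± 555 to 339 ± 191 (-3.05 ± 0.41 SE, adjusted p = 0.00677). Hoxd11 stood at 341 ± 121 in the null and 435 ± 115 in the wild type, a difference within the spread (-0.35 ± 0.35 SE, adjusted p = 0.635). In 4 of the 5 null arrays Hoxa11 lay below the median of the array, so the size of its difference depends on the offset. Whether either probe set lies within the disrupted part of its gene is not given in the sources used here, so the Hoxd11 value checks nothing about the genotype. The Notch ligand Dll1 was 4.98-fold higher in the null, at 5695 ± 1241 against 1152 ± 399 (2.32 ± 0.28 SE, adjusted p = 0.00407), and its pathway's target Hey1 was 2.04-fold higher, at 10866 ± 1400 against 5482 ± 1561 (1.03 ± 0.22 SE, adjusted p = 0.0436). Hey1 missed the threshold when any 1 array other than null replicate 1 was left out (adjusted p = 0.0558 to 0.118) and passed in 12 of 27 alternatives.

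**Figure D2:**
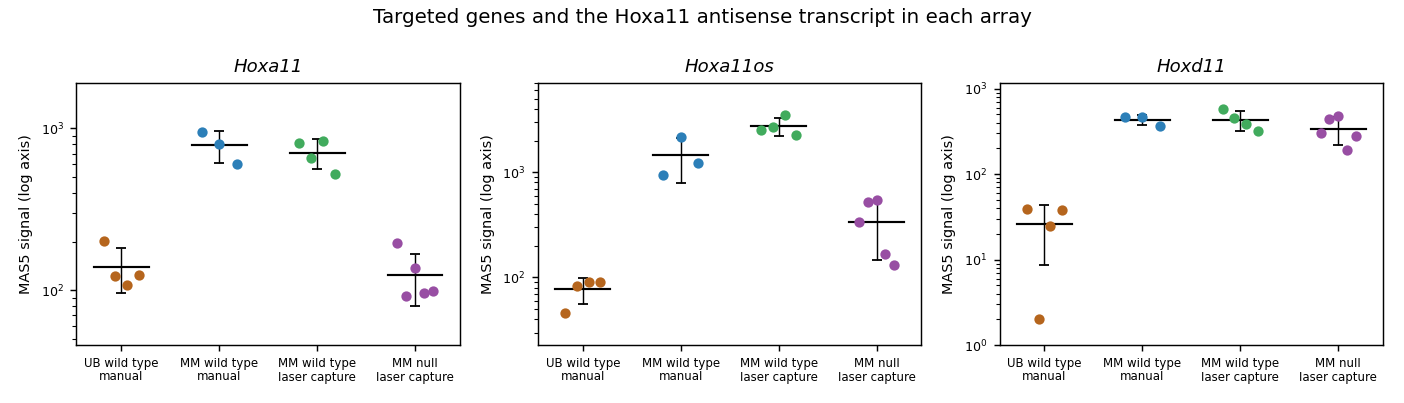
MAS5 signal (log axis) of Hoxa11, Hoxa11os and Hoxd11 in each of the 16 arrays, by group. Points are arrays, horizontal lines group means and bars ± SD; the Hoxa11 means are 139 in UB, 787 and 709 in the wild-type MM groups and 124 in the null, and the Hoxd11 mean is 341 in the null.

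In all, 138 probe sets were higher and 273 lower in the null of 23387 tested, 91 and 121 of 12161 genes. Their arrays were fully apart in 8.82% of the tested probe sets, where chance gives 1.59%. The share of higher calls depended on the scaling, since the median of all probe sets lay at -0.15: quantile normalization gave 159 higher and 243 lower, cyclic loess 158 and 184, and centring on the median 148 and 110. The count changed with the arrays left out. It was 1809 without null replicate 1, whose median correlation with its group was 0.896 where the others reached 0.928 to 0.933. It was 78, 62, 60 and 66 without wild-type captures 1 to 4. Each of these omissions leaves fewer arrays in the smaller group and loosens the filter. The count was 176, 175, 519 and 263 without null replicates 2, 3, 4 and 5.

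On the same scale, the largest decreases were for Slc26a7, an anion transporter, at 181 ± 209 against 4356 ± 2624 (log2 difference -4.62 ± 0.66 SE), Cap1, an actin regulator (-3.79 ± 0.43 SE), Tmem267 (-3.73 ± 0.31 SE), and Trim5, of a family of antiviral factors (-3.54 ± 0.48 SE). The zinc finger gene Zfp945 (-3.28 ± 0.63 SE; its other probe set 0.02, adjusted p = 0.981), Hoxa11os, the chemokine Ccl6 (-2.99 ± 0.45 SE) and the interferon-activated gene Ifi202b (-2.93 ± 0.37 SE) followed; Ifi202b stood at 5.02 ± 1.15 in the null and 288 ± 91.8 in the wild type, and with a floor in place of the offset its difference was -5.82, beyond the -5.23 of Slc26a7. The largest increases were for Cbln1, a synapse organiser (3.73 ± 0.58 SE), the neuronal filament gene Ina (3.51 ± 0.72 SE), Tmem163 (3.39 ± 0.75 SE) and Cox15, an enzyme of heme A synthesis (3.37 ± 0.48 SE). Perp, an epithelial adhesion gene, Ndnf, a secreted factor, and Rtn1, a reticulon, were higher by 3.22 ± 0.69, 3.05 ± 0.65 and 3.01 ± 0.66 SE. Rpgrip1, a ciliary protein gene, had the smallest SE of these genes, at 15970 ± 607 against 2283 ± 386 (2.80 ± 0.16 SE, adjusted p = 9.76e-06). The adjusted p of these 16 genes ranged up to 0.0470. Of the 23 genes past the threshold that are named for this comparison, 13, 14, 14 and 11 missed it without wild-type captures 1 to 4, and 0, 7, 9, 5 and 6 without null replicates 1 to 5. In the fits without null replicates 1 to 4, 22 of the 23 were tested. Hoxa11 missed it without wild-type captures 1, 2 and 3 (adjusted p = 0.0562, 0.0597 and 0.0683), with a log2 difference of -2.26 to -2.15. Over all alternatives its adjusted p ran from 2.05e-05 to 0.0821. Dll1 passed whichever array was left out. Of these omissions Tyrobp and Aldh1a3 passed only that of null replicate 1. Top2a, Ncam1 and Aldh1a3 also missed it after quantile normalization (adjusted p = 0.0524, 0.0705 and 0.0521). Among the 23 genes, 1, Tmem267, passed in every alternative, at an adjusted p of up to 0.0155.

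**Figure D3:**
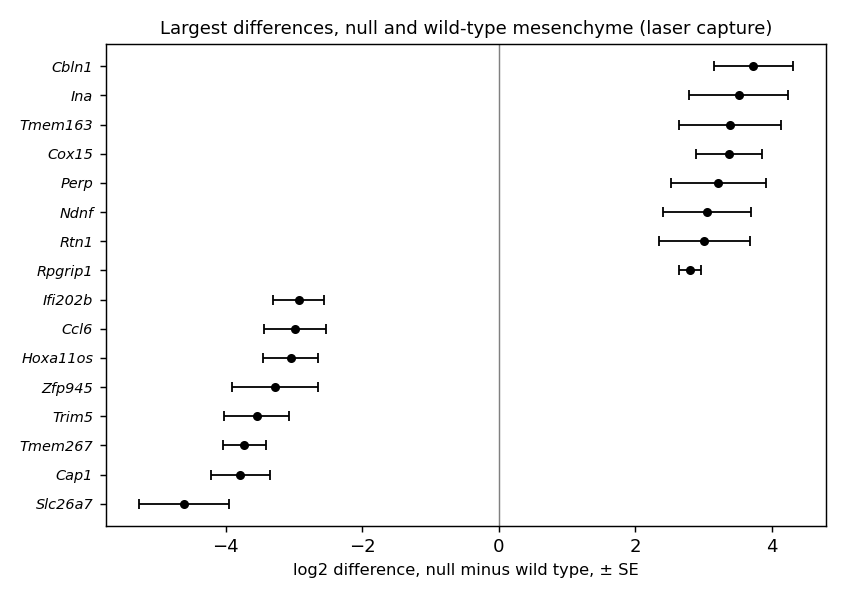
Log2 differences between null (n = 5) and wild-type (n = 4) laser-captured mesenchyme for the 8 largest increases and 8 largest decreases. Points are limma estimates and bars ± SE. The estimate is -4.62 for Slc26a7, 3.73 for Cbln1 and 2.80 for Rpgrip1; the offset sets the order of genes near background.

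Among the fixed lists, renal vesicle induction genes ranked higher in the null relative to other genes (camera adjusted p = 4.34e-05; adjusted p = 0.639 with an estimated correlation). Of 21 members 2 were called higher, Dll1 and Hey1, and 4 higher and 1 lower adjusted over the list alone, with a median of 0.60. Cell cycle genes also ranked higher, with a median of 0.21 (camera adjusted p = 5.34e-05; adjusted p = 0.639 with an estimated correlation); 1 of 27, Top2a, the topoisomerase of dividing cells, was called, at 52858 ± 2470 against 33283 ± 3782 (log2 difference 0.67 ± 0.11 SE, adjusted p = 0.0155), and 4 adjusted over the list alone. Top2a missed the threshold without wild-type captures 1, 2 and 3 (adjusted p = 0.0562, 0.0732 and 0.0656) and passed in 18 of 27 alternatives. Mcm6, a replication helicase subunit, stood at 22612 ± 3241 and 14566 ± 2718 (adjusted p = 0.0715). Hypoxia and glycolysis genes passed the list test with a median of 0.31, but with 0 of 19 called by limma on either count and 5 at an unadjusted p below 0.05 (camera adjusted p = 0.0171; adjusted p = 0.697 with an estimated correlation). Their smallest adjusted p values were 0.0826 for P4ha1, a collagen hydroxylase (0.89 ± 0.24 SE), and 0.146 for Pdk1, a kinase that restrains pyruvate oxidation (1.29 ± 0.43 SE).

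Neural crest and neuronal genes passed it with a median of 0.66, but with 0 of 13 called by limma on either count and 3 at an unadjusted p below 0.05 (camera adjusted p = 0.0355; adjusted p = 0.697 with an estimated correlation). Tubb3, a neuronal tubulin, stood at 1867 ± 1492 in the null and 407 ± 382 in the wild type (adjusted p = 0.119), and the RNA-binding Elavl3 at 708 ± 513 and 221 ± 160 (adjusted p = 0.206). This list did not pass without null replicate 1 (camera adjusted p = 0.140). Endothelial genes passed it with a median of -1.11, but with 0 of 21 called by limma, 10 at an unadjusted p below 0.05, and 1 lower adjusted over the list alone (camera adjusted p = 4.34e-05; adjusted p = 0.697 with an estimated correlation). Sox7, an endothelial transcription factor, stood at 144 ± 60.8 against 491 ± 157 (adjusted p = 0.0601) and Cd34 at 1502 ± 612 against 6024 ± 3893 (adjusted p = 0.135). Macrophage genes passed it with a median of -1.64, and with 1 of 13 called lower and 9 adjusted over the list alone (camera adjusted p = 3.96e-05; adjusted p = 0.639 with an estimated correlation). Tyrobp, an adaptor of myeloid receptors, was the member called (-2.28 ± 0.50 SE, adjusted p = 0.0470), and Laptm5 had an adjusted p of 0.0523. None of these 6 list directions changed with the 3 other scalings.

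The other 25 lists did not pass, at camera adjusted p of 0.0544 to 0.988, and 22 of them held 0 genes called by limma. In the Hox11 network of 13 measured genes 0 were called: Six2 stood at 3339 ± 3268 in the null and 4712 ± 1544 in the wild type (adjusted p = 0.421), Etv5 differed by -0.51 ± 0.34 SE (adjusted p = 0.455), Wnt11 by -0.79 ± 0.31 SE (adjusted p = 0.199) and the GDNF receptor gene Gfra1 by 0.68 ± 0.36 SE (adjusted p = 0.334). Of 20 nephron progenitor genes 1 was called, the adhesion molecule Ncam1, higher in the null at 39887 ± 8321 against 22080 ± 3385 (adjusted p = 0.0399; 1 of its 3 other probe sets at -1.48, adjusted p = 0.219), and Gas1 differed by 0.44 ± 0.15 SE (adjusted p = 0.140). Ncam1 missed the threshold without any 1 of the 4 wild-type captures (adjusted p = 0.0840 to 0.139) and without null replicates 2 and 3, and passed in 12 of 27 alternatives. Of 15 ureteric bud genes 0 were called, with Calb1 at 4302 ± 2571 against 13763 ± 10382 (adjusted p = 0.313) and Gata3 at 163 ± 128 against 470 ± 284 (adjusted p = 0.212). Of 19 stromal genes 0 were called, with Tbx18 at 1638 ± 708 against 7439 ± 4980 (adjusted p = 0.0996) and Ntn1 at 4491 ± 3721 against 977 ± 254 (adjusted p = 0.155). The retinoic acid list held 1 called gene of 11, the retinaldehyde dehydrogenase Aldh1a3, lower at 173 ± 114 against 1268 ± 921 (adjusted p = 0.0436), and 2 adjusted over the list alone. Aldh1a3 is also a bud gene, at 18601 in UB and 111.5 in hand-dissected MM. The share of bud signal implied by 56 bud genes averaged 3.18 ± 3.24% in the null and 6.38 ± 4.49% in the wild-type captures (two-sided exact permutation p = 0.222). Each share is a median over these genes. Their lower quartile was negative in null captures 1, 2 and 3 and positive in the other captures. The p53 and apoptosis list held 1 called gene of 12, Perp. Adjusted over the list alone, the counts were otherwise 0 to 3 in either direction.

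With 0 members called by limma were also the epithelial, matrix, Hoxa, Hoxb, Hoxc, Hoxd, Ret and FGF, Wnt, hedgehog, BMP and TGF-beta, immediate-early, erythroid, gonad, germ cell, adrenal, muscle, smooth muscle, posterior and sex-linked lists. Over the 25 lists without a called member, the 3 passing ones included, 29 of 309 entries were higher and 34 lower at an unadjusted p below 0.05. Of all tested probe sets, 4368 of 23387 had an unadjusted limma p below 0.05, so these lists stood near the share of the whole. The medians of the epithelial, nephron progenitor, Wnt, BMP and germ cell lists differed in sign from their tests, and the medians of the germ cell and p53 lists from their means. In the 5 null captures the own-group correlation of arrays averaged 0.924 against 0.956 in the 4 wild-type captures. Its two-sided exact permutation p was 0.00794 (adjusted over 18 tests 0.0735). Arrays of a group share the pairs behind these values, so the values are not independent and this p does not measure the difference. The spike-in control signal averaged 13360 in the null and 9534 in the wild-type captures (two-sided exact permutation p = 0.0556, adjusted 0.125).

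Isolation method was compared within wild-type samples labelled as mesenchyme, taken by laser capture and by hand. Per the labels the captures pooled 3 to 4 mesenchymes and the hand-dissected samples were individual ones. Pooling therefore differs together with method. The bud gene Calb1 was 57.0-fold higher in laser-captured MM, at 13763 ± 10382 (SD, n = 4) against 155 ± 27.3 (SD, n = 3; log2 difference 5.83 ± 0.51 SE, limma adjusted p = 0.000143). Over the alternatives the Calb1 difference ran from 5.20 to 6.34. Esrp1 stood at 3011 ± 2324 against 25.2 ± 15.6, which lies below the offset, so its difference of 5.34 ± 0.52 SE depends on the offset. In the other direction the immediate-early gene Fosb, a transcription factor subunit induced within minutes of a stimulus, stood at 73.5 ± 59.0 in laser-captured and 17990 ± 2918 in hand-dissected MM (-7.54 ± 0.43 SE), and Fos at 320 ± 310 and 32684 ± 5142 (-6.92 ± 0.54 SE). Hoxa11 and Hoxd11 differed by -0.14 ± 0.27 SE (adjusted p = 0.728) and -0.03 ± 0.28 SE (adjusted p = 0.956).

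In all, 3857 probe sets were higher and 2009 lower in laser-captured MM of 23612 tested, 1659 and 1202 of 12172 genes. Groups did not overlap in 35.2% of the probe sets, where chance gives 5.71%. The split again depended on scaling, with the median of all probe sets at 0.11: quantile normalization gave 2924 higher and 2551 lower, cyclic loess 3167 and 2485, and centring on the median 2238 and 3661. For 159 called genes another probe set was called in the opposite direction, and the count fell to 3384 without hand-dissected replicate 7.

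Of 15 ureteric bud genes 9 were higher in the laser captures, with 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000561; adjusted p = 0.864 with an estimated correlation). Besides Calb1 these included Mal (log2 difference 3.24 ± 0.49 SE) and the transcription factors Gata3 (2.39 ± 0.45 SE) and Emx2 (2.29 ± 0.38 SE). Ret stood at 3163 ± 3062 against 208 ± 33.4. Of 23 epithelial genes 17 were higher, and 20 adjusted over the list alone (camera adjusted p = 1.33e-08; adjusted p = 0.864 with an estimated correlation), among them Cldn3 (4.19 ± 0.59 SE), Cldn7 (4.10 ± 0.54 SE) and the cadherin Cdh1 (3.50 ± 0.50 SE). Aldh1a1 (3.43 ± 0.63 SE), the zinc finger gene Zfp934 (3.32 ± 0.37 SE) and the keratin Krt8 (3.24 ± 0.48 SE) complete the 8 largest increases on this scale. Renal vesicle induction genes were higher in 7 of 21 on either count, including Pou3f3 (3.22 ± 0.46 SE) and the Wnt inhibitor Dkk1 (1.67 ± 0.34 SE; camera adjusted p = 0.0360; adjusted p = 0.864 with an estimated correlation).

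Of 28 immediate-early and stress genes 17 were lower and 1 higher on either count (camera adjusted p = 6.33e-10; adjusted p = 0.864 with an estimated correlation). All 8 of the largest decreases on this scale were members of this list: besides Fosb and Fos, the zinc finger factors Egr2 (log2 difference -5.72 ± 0.63 SE), Egr3 (-4.29 ± 0.64 SE), Egr1 (-4.01 ± 0.26 SE) and Klf4 (-2.89 ± 0.32 SE), the nuclear receptor Nr4a1 (-2.86 ± 0.46 SE), and Zfp36, which destabilises cytokine mRNAs (-2.39 ± 0.22 SE). Of 12 erythroid genes 6 were higher, and 7 adjusted over the list alone, with the embryonic globin Hbb-y at 0.66 ± 0.10 SE and Klf1, an erythroid transcription factor, at 1.65 ± 0.34 SE (camera adjusted p = 0.00510; adjusted p = 0.864 with an estimated correlation). Of 12 macrophage genes 4 were higher, and 6 adjusted over the list alone, with the complement gene C1qa at 3.19 ± 0.47 SE and Tyrobp at 1.78 ± 0.39 SE (camera adjusted p = 0.00648; adjusted p = 0.864 with an estimated correlation). These 6 list directions kept their sign under the 3 other scalings.

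**Figure D4:**
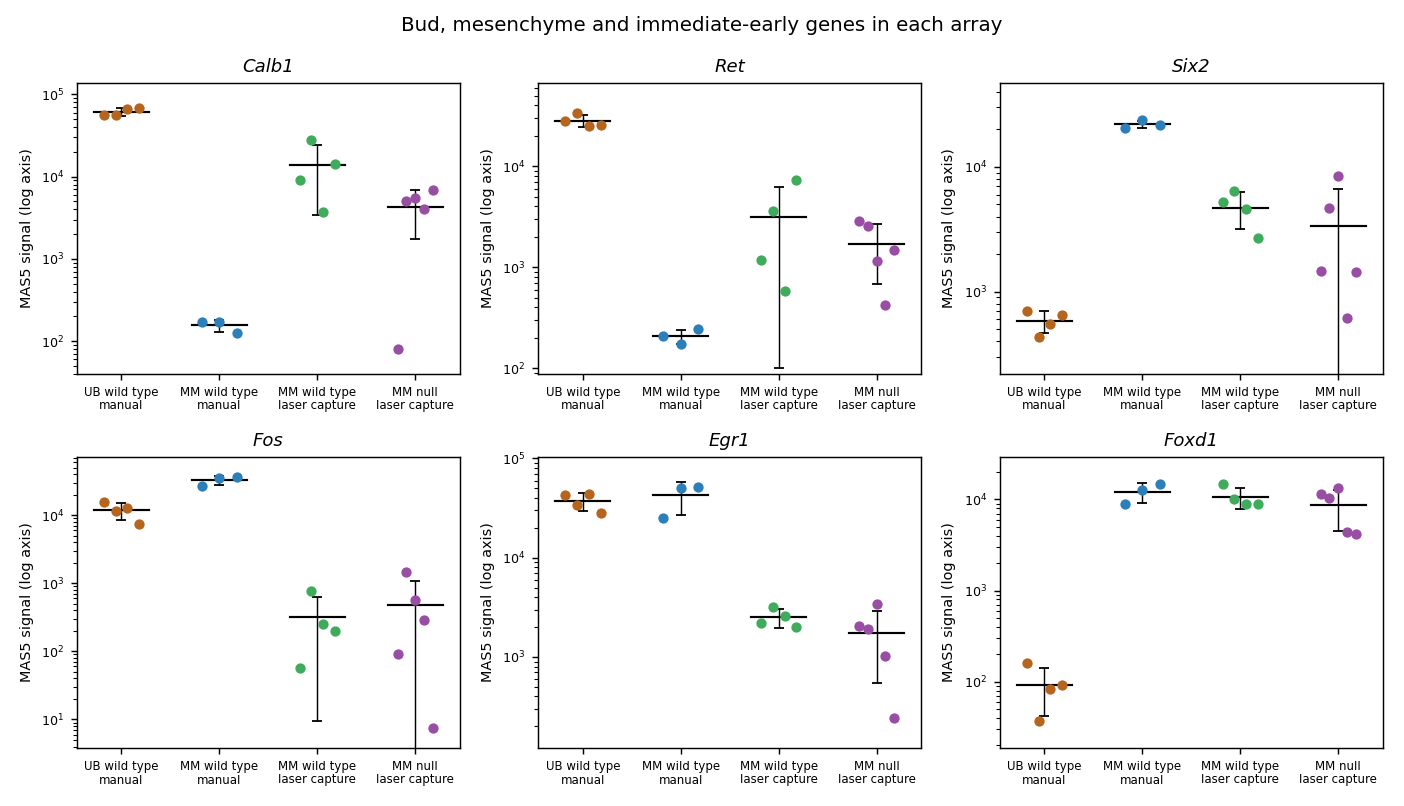
MAS5 signal (log axis) of Calb1, Ret, Six2, Fos, Egr1 and Foxd1 in each of the 16 arrays, by group. Points are arrays, horizontal lines group means and bars ± SD, which run off the lower edge where the SD nears the mean; mean Calb1 is 155 in hand-dissected and 13763 in laser-captured wild-type MM, and mean Fos 32684 and 320.

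The other 25 lists did not pass, at camera adjusted p of 0.106 to 0.997. Of 19 nephron progenitor genes 5 were lower and 2 higher, with 6 and 2 adjusted over the list alone. Six2 stood at 4712 ± 1544 in laser-captured and 21975 ± 1549 in hand-dissected MM (log2 difference -2.28 ± 0.25 SE, adjusted p = 0.000345), and Hoxc10 at 5881 ± 711 and 18362 ± 1290 (-1.64 ± 0.15 SE). Of 19 stromal genes 2 were higher and 4 lower on either count. The Hox11 network had 2 higher and 1 lower of 12, with 2 and 2 adjusted over the list alone, and Ret and FGF targets 1 and 5 of 16, with 2 and 6. Called higher and lower were further 4 and 1 of 11 retinoic acid, 2 and 3 of 27 cell cycle and 1 and 0 of 21 endothelial genes. Hoxb, Hoxd, germ cell, posterior and sex-linked lists held 0 calls by limma, with 3 of their 26 members at an unadjusted p below 0.05, and the remaining lists 1 to 4 each. Of all tested probe sets, 9053 of 23612 had an unadjusted limma p below 0.05. The stromal, Hox11 network, Hoxc, BMP, hedgehog, matrix, Hoxd, cell cycle and germ cell lists had medians, means or tests of differing sign. Array measures moved with the method as well. The 18S ribosomal signal averaged 5414 in laser-captured and 602 in hand-dissected MM, the spike-in control signal 9534 and 4748, and the median signal 173 and 147. Each had a two-sided exact permutation p of 0.0286, the smallest that 35 splits allow (adjusted over 18 tests 0.0735). The 3' to 5' ratio averaged 19.8 and 42.5 for Gapdh and 17.1 and 13.8 for Actb (two-sided exact permutation p = 0.0857 and 0.229). The own-group correlation averaged 0.956 and 0.970.

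The contrast of UB with MM and that of null with wild type share no arrays, and their relation asks whether bud or mesenchyme genes move together in the null. Across 11690 genes the log2 differences correlated weakly (Pearson r = 0.10, Spearman rho = 0.12); genes are not independent replicates. Of 1483 genes higher in UB and 119 lower in the null, 7 were shared where independence gives 15.1 (odds ratio 0.427, Fisher's exact p = 0.0255, adjusted over the 4 directions 0.102). Genes higher in UB and higher in the null shared 16 against 10.8 (odds ratio 1.60, adjusted p = 0.200). For genes lower in UB, 15 were shared with those higher in the null against 12.8, and 22 with those lower against 17.97 (odds ratios 1.21 and 1.28, adjusted p = 0.542 and 0.404). None of the 4 passed the adjustment. Without null replicate 1 all 4 did, and 1 turned: the odds ratio of genes lower in UB and higher in the null was 0.524 (adjusted p = 0.000628), and that of genes higher in UB and lower in the null 0.368 (adjusted p = 4.95e-07). With a filter at the 75th percentile the odds ratio of genes lower in UB and higher in the null turned too, to 0.687 (Fisher's exact adjusted p = 0.309).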

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

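Among the tests below, those of a raised background, of bud cells for the immediate-early genes, of array-wide scaling and of null replicate 1 were chosen after the result was seen. A gap test compared each array with the others of its group, for array measures and for the genes named in the report. It covered groups of 4 or 5 arrays, so the 3 hand-dissected mesenchyme arrays were not tested. Of 177 groups tested, 12 held an array far from the rest. This is close to the share of about 5 percent that chance gives, so single flags may be chance. Null replicate 1 stood apart in 4 of the 12 groups. Its median signal was 209.2 (others 112.7 to 128.9), its median correlation with its group 0.896 (0.928 to 0.933), its log2 value of Zfp945 8.13 (5.31 to 5.50) and that of Calb1 6.85 (11.99 to 12.76). UB replicate 1 stood apart in log2 values of Cldn7, 14.52 (14.97 to 15.06), Gas1, 12.65 (11.92 to 12.00), and Fosb, 12.54 (10.65 to 10.79). UB replicate 2 had a log2 value of Kdr of 8.11 (8.95 to 9.12), and UB replicate 4 an 18S ribosomal signal of 4811.1 (892.8 to 1141.7). Null replicate 5 had a log2 value of Tmem163 of 6.16 (9.15 to 10.30). Wild-type capture 3 had a log2 value of Ndnf of 9.21 (8.42 to 8.52), and wild-type capture 1 one of Hey1 of 11.65 (12.53 to 12.70).

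Genes of the ureteric bud were higher in laser-captured than in hand-dissected wild-type mesenchyme. Bud cells captured with the mesenchyme are a candidate explanation: over 56 genes at least 32-fold higher in UB, the implied share was 6.91% from 1 part of the genes, and 89.3% of the other part reached at least 0.5 of the level this share needs. Both parts were measured on the same arrays, so any cause that raised these genes together could give this result. The split therefore does not favour bud cells over such a cause. The implied shares of the 20 most abundant ran from 2.95 to 22.2%, with a median of 7.18%. A raised background of dim probe sets is argued against as the whole cause. The median difference of the bud and epithelial lists was 1.98, and that of genes matched on signal 0.53. It exceeded the latter by 1.45, with 0 of 1000 random draws as large. The matched genes rose as well. However, a gene dim in every hand-dissected array passed the filter only if it was above the median in enough laser captures. The listed genes passed the same filter. The rise of the matched genes therefore cannot show whether a raised background holds a part. The draws ignore correlation between genes, estimated at 0.33 and 0.58 in these lists, and so overstate the evidence. No biological explanation was tested, because isolation method is not a biological group.

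Immediate-early genes were lower in laser-captured than in hand-dissected wild-type mesenchyme. Dilution by bud cells at the level of the hand-dissected buds is argued against. For 14 of the 17 members called lower, every laser-captured wild-type array lay below all 7 hand-dissected arrays, those of the bud included. No array holds laser-captured buds, so the level in captured bud cells is not known and dilution by them was not tested. Array-wide scaling is argued against as well, since the median difference lay at -1.40 relative to genes matched on signal, with 0 of 1000 random draws as large. These draws also ignore correlation between genes, estimated at 0.31 in this list. Induction during handling by hand may also account for it and cannot be told apart, since 14 of the 17 were lower in every null array as well, and the explanation coincides with the method compared. No biological explanation was tested.

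The last pattern is the set of genes called between null and wild-type captures. Low quality of null replicate 1 as the whole cause is argued against, since 1809 probe sets were called without it. Sequence variants under single probe sets cannot be told apart from changed expression: the gene's other probe set showed a median 0.496 of the difference (95% bootstrap interval 0.239 to 0.662, 64 genes), against 0.681 for UB and MM and 0.391 for the isolation methods. Chromosome segments of another strain beside the targeted loci stay open too: 9 of 200 neighbours were called against 201 of 11930 other genes (odds ratio 2.75, interval 1.22 to 5.43, Fisher's exact p = 0.0081), and genotype itself could act on neighbours. Genotype, source piece and pooling differ together, so none of them is excluded, and strains are not given in the sources used here.

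Chance was tested by other splits of the same arrays into groups of the same sizes. For UB and MM, 1 of 35 splits gave a count as large as 5701, the real one, and the highest other was 3362, with UB replicate 1 placed among the mesenchymes. For null and wild type it was 1 of 100 splits drawn from 126, with 411 and 57. For the isolation methods it was 1 of 35 splits, with 5866 and 2185. In each case the real grouping gave the highest count of the splits tried. So few splits make chance less likely for these 3 counts but cannot exclude it.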

How the results depend on the processing

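The fits without null replicate 1 of the lists, of the relation between contrasts and after quantile normalization, and the fit of replicates 1 to 4 without their number, were chosen after the data were seen. Apart from the values below and the left-out arrays named in the report, counts of called probe sets stayed within 1.5 times the count in the report. Where a count moved, the cause was not tested, except where fewer probe sets or arrays entered. No detection calls were used here, which limits what can be said of probe sets near background.

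For UB against MM (5701), the count was 3171 with a filter at the 75th percentile, 10132 with array weights, 3580 with all 16 arrays in 1 fit and 2488 by an unequal-variance test with adjustment. It ran from 3982 to 7804 when 1 array was left out. Of 53 named genes past the threshold, 46 stayed past it in every alternative that tested them, and 0 lost it when 1 array was left out. Fos and Fosb reversed against all 7 wild-type MM arrays, to 2.46 (adjusted p = 0.335) and 1.36 (adjusted p = 0.661).

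For null against wild type (411), it was 258 with arrays centred on their medians, 250 with a floor in place of the offset, 256 without a filter, 215 without an intensity trend, 1654 with array weights and 1793 with all 16 arrays in 1 fit. It was 53 by the unequal-variance test and 4043 by that test unadjusted, 1538 against all 7 wild-type MM arrays, and 1402 after quantile normalization without null replicate 1. Leaving out 1 array gave 60 (without wild-type capture 3) to 1809 (without null replicate 1). Of 23 named genes past the threshold, 1, Tmem267, stayed past it in every alternative. With a replicate block over replicates 1 to 4 the count was 54, against 263 for the same arrays without it; same-number correlations ran from -0.047 to 0.074 and 0 of 4 wild-type arrays correlated best with their own number, so the numbers give no pairing.

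For laser capture against hand dissection (5866), it was 2811 with all 16 arrays in 1 fit, 3281 with a 2-fold minimum and 873 by the unequal-variance test, and 3384 (without hand-dissected replicate 7) to 5994 (without wild-type capture 3) with 1 array left out. Of 28 named genes past the threshold, 9 stayed past it in every alternative that tested them, and 0 lost it when 1 array was left out.

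With the inter-gene correlation estimated, the number of lists past the threshold was 2 for UB and MM, in place of 15, and 0 in each of the other comparisons, in place of 6. The odds ratio of genes higher in UB and lower in the null was 0.272 after quantile normalization (adjusted p = 0.0173; 4.95e-07 to 0.102 over its alternatives). Without null replicate 1, the odds ratios were 1.495 (higher in UB and higher in the null), 0.368 (higher and lower), 0.524 (lower and higher, which turned its direction) and 1.81 (lower and lower).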

Other observations

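The sex-linked genes give the make-up of single samples. Xist, which is transcribed from the inactive X chromosome of females, and Eif2s3y, a gene of the Y chromosome, were both high in the 4 UB pools, at 20689 to 30784 and 1058 to 2028.6. Among the hand-dissected mesenchymes, replicate 5 had 30402 and 1.4, replicate 6 172.1 and 3722.9, and replicate 7 18682 and 2487.5, although the labels describe individual mesenchymes. The 4 wild-type captures held both, at 2760.9 to 51035 and 1128 to 3322.5. Of the null captures, replicates 1 and 5 had Xist at 29 and 173.1 with Eif2s3y at 2749.7 and 1747.5, and replicates 2, 3 and 4 had Xist at 36583, 39305 and 4317.9 with Eif2s3y at 6.5, 6.3 and 15.

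The share of bud signal implied by 56 bud genes was 3.83, 10.98, 1.44 and 9.28% in wild-type captures 1 to 4 and 2.09, 1.90, 0.904, 2.07 and 8.91% in null captures 1 to 5. The means were 6.38 ± 4.49% (SD, n = 4) and 3.18 ± 3.24% (SD, n = 5; two-sided exact permutation p = 0.222). The lower quartile over these genes was 2.49, 8.45, 0.72 and 6.66% in wild-type captures 1 to 4. In null captures 1 to 5 it was -0.04, -0.27, -0.35, 0.50 and 3.91%. A single share therefore does not describe all 56 genes in null captures 1, 2 and 3.

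The neighbours of the targeted loci called between null and wild-type captures are given here although they were chosen after their values were seen. Near Hoxa11 they were Zfp467 (log2 difference -1.17), Tra2a (-0.82), Kbtbd2 (-1.14) and Lancl2 (-1.48), lower in the null, and Ndnf, higher (3.05). Near Hoxd11 they were Spc25, a kinetochore gene (-1.51), lower, and Metap1d (1.53), Frzb, a secreted Wnt antagonist (2.56), and Tmx2 (0.84), higher.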
